A study of Danio rerio with 2 samples.

How the data were processed

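Single-cell suspensions of whole zebrafish embryos at 48 hpf, from about 200 embryos per genotype, were processed with the 10x Genomics Chromium 3' kit (v3.1) and sequenced on a NovaSeq instrument, per the labels' protocols and the series design. There was 1 wild-type and 1 rars2 mutant library, both labelled as batch 1, and grouping followed the genotype label. The deposited values were raw UMI counts per gene and barcode, made by the authors with Cell Ranger 6.0.1 against GRCz11, and Seurat 4.1.0 was used for later steps, per the submitters' processing notes. The authors' cell filter and cell type annotation are not given in the sources used here. The matrices held 27429 genes, of which 9723 carried an identifier in place of a symbol, and 7222 of these were named from a gene name table. Barcodes had 17 characters and at least 500 UMIs, and the largest had 65051 and 40168 UMIs. No genome was used, so no coordinates are given.

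Barcodes were kept with at least 500 genes, at most 20% of UMIs from mtDNA-encoded genes and at most 60000 UMIs. This removed 2670 (15.6%) wild-type and 2558 (17.6%) mutant barcodes for genes, 7 and 3 for mtDNA and 2 and 0 for UMIs. Scrublet (in scanpy 1.11.5, expected doublet rate 8%) called 0 doublets in both libraries at automatic thresholds of 0.445 and 0.565. A caller that marks under 0.5% of so many cells has not worked, so doublets remain in the data, and the barcodes with the highest 8% of scores were removed as an alternative. Counts were scaled to 10000 UMIs per cell and log-transformed. The analysis used 2000 variable genes without mitochondrial, ribosomal, hemoglobin, heat shock and immediate early genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1.5 (leidenalg 0.10.2, igraph 0.11.9), with both libraries together and no integration. Neural cells were clustered again with 30 components at resolution 1.0. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

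Of 46 clusters 36 were named from marker lists, 5 stayed unnamed and 5 had the markers of a class but came almost wholly from 1 library. A class needed at least 3 markers at least 2-fold above other clusters at 15 CPM or more, and a leading class within 5% of another was read as a tie. Clusters with more than 90% of cells from 1 library, of which there were 7, were given by number. That rule was set at the outset, set aside during the work and then restored, and the version with those clusters kept in their classes is an alternative. The rule that names clusters was changed 3 times after its names were seen, and 40 of the 46 clusters had the same name under all 4 versions. Clusters 4, 5, 6, 19 and 44, all counted as neural here, were unnamed under version 1. Clusters 4, 5 and 6 held 166, 254 and 171 wild-type and 1098, 1002 and 1042 mutant cells. Clusters 19 and 44 held more wild-type than mutant cells. Candidate names of the 27 neural sub-clusters were also extended after they were seen, and 3 sub-clusters stayed unnamed or by number. Neural cells are the clusters with markers of neural progenitors, neuronal precursors, neurons, retinal progenitors or retinal neurons. The neuron, neuronal precursor and retinal neuron classes contained clusters whose leading genes held more markers of another class, so their clusters were compared by number. Sizes of clusters compared by number are given beside those of the best-overlapping cluster formed without genes that differed at least 1.5-fold between libraries. Overlap is the share of cells found in both clusters among cells in either. It was low for many clusters, such as 22.9% for cluster 23, so matched sizes can describe largely other cells. For neural sub-clusters the matching was added after their shares were seen.

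UMIs were summed per library and class and given as CPM. Ratios of UMI levels have exact conditional binomial intervals, levels exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. Ratios of shares have a range from opposite ends of the share intervals of both libraries, which is wider than a 95% interval. Cells and genes are not replicates, so no p-value, standard error or number of changed genes was derived from them. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs. A gene with 0 UMIs in 1 library was set against 3 UMIs. The 52 gene lists, the markers, the rule for named genes and most alternatives were fixed before the data were examined, and 51 lists gave a value, since the list of mtDNA-encoded rRNA genes had no member in the matrices. For each list, members with at least 50 UMIs were counted as at least 1.25-fold higher, at least 1.25-fold lower or between. The list median was set against 10000 random lists of the same size matched on expression in 20 bins, with intervals from 1000 Poisson draws. Scaling by the median gene moved all list medians by the same amount, and counts relative to the median gene are printed where they move the split of higher and lower by over 10 percentage points.

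Genes were named by size alone. Besides rars2, these were the 10 highest and 10 lowest median ratios, past 1.25-fold, among genes with at least 30 UMIs in at least 5 cell groups and the same sign in at least 80% of them. In neural progenitor-like cells, clusters 6 and 3, which stood in for neuronal precursors and neurons, and the 3 largest other classes, the rule took the 5 highest and 5 lowest ratios among genes with at least 100 UMIs whose interval lay wholly past 1.25-fold. In each list it took the 3 members with the largest ratios in neural cells. Some genes, and 1 list with its tests, are not reported here. Genes with near-identical copies, such as globin, crystallin, her4 and opsin genes, may share reads, and how these were split is not given in the sources used here.

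The procedure was tested on simulated Poisson counts with 200 changed genes, where all other genes had the same mean in both libraries. The draws held no variation between cells, pools or libraries. They check the counting intervals, not how often genes pass the size rule without a genotype difference in these data. In neural progenitor-like cells (10094 genes) 41.8%, 86.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold passed the size rule, with 6 of 9894 unchanged genes, and 95.5% of intervals covered the true ratio. In neural cells (16503 genes) the shares were 64.2%, 95.5% and 100%, with 8 of 16303 unchanged genes. Simulated lists of 20 genes raised 1.5-fold lay above all random lists, and unchanged lists at the 7.92 and 72.1 percentiles.

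Alternatives covered the cell filter, clustering resolution, clustering without differing genes, transfer of wild-type clusters to mutant cells, marker scores per cell, scaling, thinning, equal weights per cluster or cell, list minima and bins, and, added after the data were seen, doublet scores, clusters mostly of 1 library, earlier naming rules, low-depth clusters, a mesenchyme-marked neural sub-cluster and subtraction of a background profile. That profile came from barcodes with fewer than 500 genes. It was subtracted only in neural cells and in neural classes and clusters, at 13.6% to 23.8% of their UMIs, the share that genes of absent cell types allowed. An alternative counted as moved when it left the counting interval of the main value. The lists and shares followed through all alternatives were picked after their values were seen.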

Results

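Whole zebrafish embryos were profiled by single-cell RNA sequencing at 48 hours post fertilization (hpf), when brain regions are laid out and the retina and spinal cord are still adding neurons. There was 1 library of wild-type embryos and 1 library of rars2 mutant embryos, each made from about 200 pooled embryos and both labelled as batch 1. The gene rars2 encodes the mitochondrial arginyl-tRNA synthetase, the enzyme that charges the arginine tRNA used in mitochondrial protein synthesis. Variants in its human counterpart are linked to pontocerebellar hypoplasia, a disorder of hindbrain growth, and the series title asks about the fate of neural cells. The deposited matrices held 17134 barcodes with 66415050 unique molecular identifiers (UMIs) for wild type and 14565 barcodes with 55155178 UMIs for the mutant. Filtering kept 14455 and 12004 cells, with medians of 3855 and 4008 UMIs and 1759 and 1775 genes per cell. There were no replicate libraries, so every value compares these 2 libraries rather than the genotypes. Intervals are 95% exact intervals, except for ratios of shares, whose ranges are wider, and list medians, which used Poisson draws. All cover counting error only.

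The targeted transcript was not lower in the mutant library. Over all kept cells rars2 (ENSDARG00000032277) had 278 UMIs in wild type and 290 in the mutant, or 4.29 (3.80 to 4.83) and 5.40 (4.80 to 6.06) CPM (counts scaled to the library total). The ratio of mutant to wild type was 1.26 (1.06 to 1.49), with a log2 ratio of 0.32 over all deposited barcodes. In neural cells, where 95 and 199 UMIs were counted, the ratio was 1.03 (0.803 to 1.33). It was 1.27 (0.682 to 2.53) in neural progenitor-like cells, 1.15 (0.447 to 3.78) in retinal progenitor-like cells and 2.34 (1.29 to 4.25) in fibroblast-like cells. Muscle progenitor-like, fin fold-like, pharyngeal arch-like and basal epidermis-like cells gave 1.06, 1.08, 0.859 and 0.833, and neural clusters gave 0.574 (cluster 30) to 2.84 (cluster 10), all with intervals that included 1. The ratio of basal epidermis-like cells rested on only 5 and 1 UMIs. Endothelium-like, erythroid-like, pigment cell-like, skeletal muscle-like and macrophage-like cells had at most 3 UMIs in each library, and their ratios are not given. The labels do not describe the lesion, and a 3' tag outside it would be counted in both genotypes, so this level does not check the genotype labels.

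Neural cells made up a larger part of the mutant library. They were 3565 of 14455 wild-type cells, or 24.7% (24.0 to 25.4), and 6829 of 12004 mutant cells, or 56.9% (56.0 to 57.8), a ratio of 2.31. Neural progenitor-like cells, which carry sox19a and Notch-driven her genes, were 3.18% (2.9 to 3.5) and 13.6% (13 to 14) of all cells, a ratio of 4.27. Retinal progenitor-like cells, which carry rx1 and foxn4, were 1.15% (0.981 to 1.34) and 9.15% (8.64 to 9.68). Connective tissue, skin, muscle wall and blood-cell classes were mostly smaller in the mutant library, as the plot of class shares shows. Because marker genes themselves differed between libraries, cells were also clustered without every gene that differed at least 1.5-fold over all cells. The log2 ratio of the neural share then went from 1.21 to 0.71 and that of neural progenitor-like cells from 2.09 to 2.01, while no cluster was named retinal progenitor-like. Under version 1 of the naming rule, changed after its names were seen, the log2 ratio of the neural share was 0.64. Cluster 4, the only retinal progenitor-like cluster, was unnamed in that version. Classes were also assigned cell by cell from marker scores, which gave 2.84 for neural progenitor-like cells and 1.09 for retinal progenitor-like cells, against 2.99 from clusters. Unnamed clusters and clusters almost wholly of 1 library held 39.9% of wild-type and 24.8% of mutant cells. Most of these were in clusters 0 (2909 and 21 cells) and 1 (139 and 2650), which had medians of 806.5 and 811 UMIs and fell in a shared cluster of 3217 and 2593 cells (22.3% and 21.6%) without the differing genes.

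**Figure D1:**
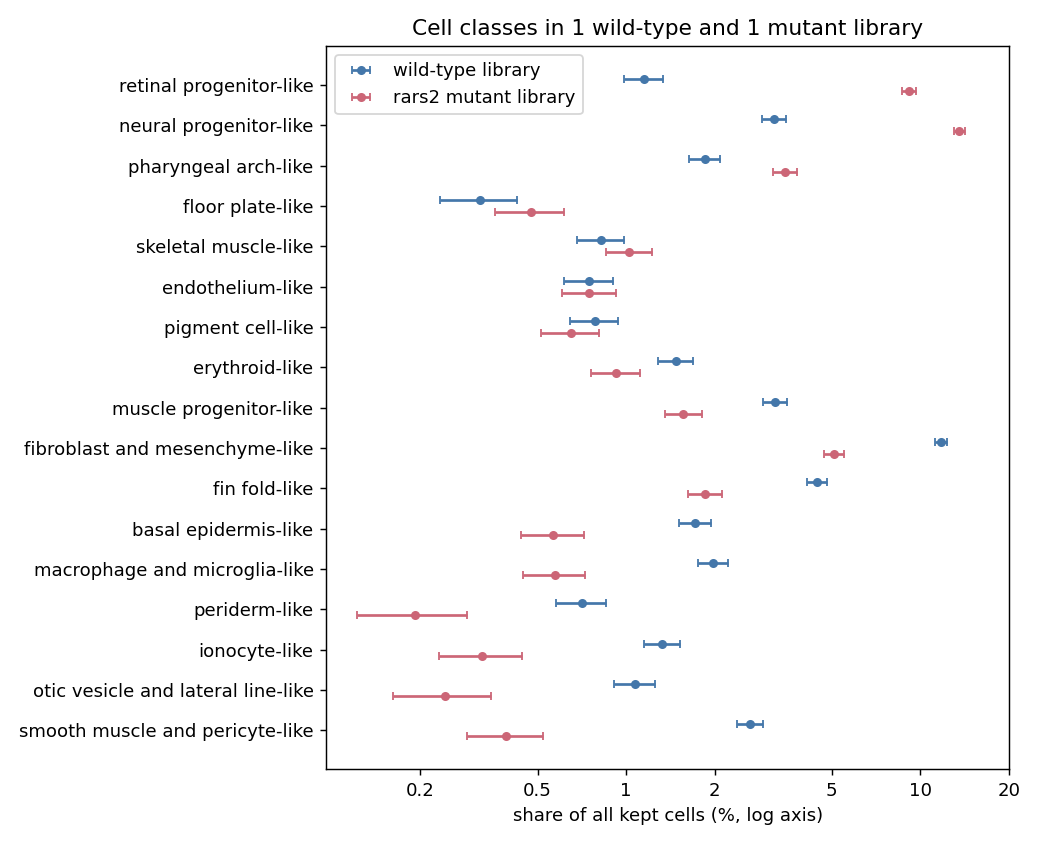
Share of all kept cells in each named class (percent, log axis) in the wild-type library and the rars2 mutant library, with 95% exact binomial intervals for counting error; the lens and neutrophil classes and clusters compared only by number are left out. All neural cells together are not plotted. Neural progenitor-like cells lie at 3.18% and 13.6%, and smooth muscle and pericyte-like cells at 2.64% and 0.392%.

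Outside the nervous system, fibroblast-like cells, which carry collagens and lum, were 11.7% of wild-type and 5.07% of mutant cells. Fin fold-like cells, with the actinodin genes and1 and and2, were 4.46% and 1.86%, and smooth muscle and pericyte-like cells, with acta2 and tagln, were 2.64% and 0.392%. Macrophage-like cells were 1.97% and 0.575%, ionocyte-like cells 1.33% and 0.325%, and neutrophil-like cells 87 and 11 cells. Among epithelia, basal epidermis-like cells were 1.72% and 0.567%, periderm-like cells 0.706% and 0.192%, and otic vesicle and lateral line-like cells 1.07% and 0.242%. Muscle progenitor-like cells were 3.21% and 1.57%. Endothelium-like cells (0.75% in both), pigment cell-like cells (0.782% and 0.650%), skeletal muscle-like cells (0.823% and 1.02%) and floor plate-like cells (0.318% and 0.475%) had ratios whose intervals included 1, and lens-like cells numbered 3 and 14.

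Clustering without the genes that differed kept the lower share of several of these classes. The log2 ratio was -1.50 for basal epidermis-like cells, -1.79 for periderm-like cells, -1.59 for smooth muscle-like cells against -2.75 in the main clustering, and -2.62 for fibroblast-like cells against -1.21. It was -0.93 for otic-like cells against -2.15. Endothelium-like, pigment cell-like, skeletal muscle-like, floor plate-like and lens-like cells gave -0.35, 0.03, -0.44, 0.82 and 2.17. The fin fold-like cluster 14 and muscle progenitor-like cluster 29 fell, with fibroblast-like cluster 11, in a shared cluster of 941 and 299 cells (6.51% and 2.49%). Fin fold-like cluster 27 shared 493 and 145 cells (3.41% and 1.21%) with the basal epidermis-like and otic-like clusters. The macrophage-like, neutrophil-like and erythroid-like clusters had the same best match, with 511 and 112 cells (3.54% and 0.933%). The erythroid-like cluster overlapped it by only 12.2%, so these sizes say little about erythroid-like cells. The ionocyte-like cluster matched 46 and 20 cells (0.318% and 0.167%), at an overlap of 28.6%. Muscle progenitor-like cluster 20 and the skeletal muscle-like cluster matched 337 and 207 cells (2.33% and 1.72%).

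Among classes whose interval did not include a ratio of 1, the direction of 2 depended on how cells were classed. Erythroid-like cells were 1.47% and 0.925%, a log2 ratio of -0.67, but 1.51 with marker scores per cell and 2.55 at Leiden resolution 0.8. Pharyngeal arch-like cells were 1.85% and 3.47%, a log2 ratio of 0.90, but -1.33 with clustering that left out the differing genes. Cluster 8, which carries the arch genes dlx4a, barx1 and gsc and came almost wholly from wild type (1008 and 29 cells; 1805 and 438 matched), was not counted in that class, and with such clusters counted the log2 ratio was -1.3. Classes whose interval included 1 also took either sign over the alternatives, from -0.51 to 3.01 for skeletal muscle-like, -0.23 to 0.82 for floor plate-like, -0.53 to 0.03 for endothelium-like and -1.02 to 0.03 for pigment cell-like cells.

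Several cell types that mature late were scarce in the mutant library. The cluster with the cone opsin genes opn1sw1 and opn1lw2 and the cone arrestin gene arr3a held 438 wild-type and 19 mutant cells, and 342 and 16 cells (2.37% and 0.133%) in the matched cluster formed without differing genes. Cartilage-like clusters 15 and 28, led by matn1, col11a2 and acana, held 440 and 26 and 253 and 21 cells, and matched a shared cluster of 433 and 35 cells. Cluster 43, with the same cartilage genes, held 44 wild-type cells and 0 of 12004 mutant cells (interval up to 0.0307%), but its best match, at an overlap of 4.53%, held 440 and 231 cells. Cells with the myelin genes mbpb, mag and cldnk numbered 287 and 70 (260 and 57 in the matched cluster, or 1.80% and 0.475%). Bipolar-like cells with vsx1 numbered 487 and 205 (450 and 191, or 3.11% and 1.59%).

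Several clusters with genes of neurons, neuronal precursors or photoreceptor precursors were larger in the mutant library, and others were similar or smaller. Cluster 6, led by the transcription factor genes lhx9, barhl1a, lef1 and nhlh2, held 171 wild-type and 1042 mutant cells, and its matched cluster 164 and 1327 cells (1.13% and 11.1%); 0 of its 10 leading genes differed between libraries by the 1.5-fold rule. Cluster 23, with hoxb8a and tlx2, held 42 and 303 cells (85 and 225 matched, at an overlap of 22.9%). Cells with the photoreceptor precursor genes crx, nr2e3 and otx5 numbered 72 and 164 (87 and 172 matched, or 0.602% and 1.43%). Clusters 3 and 5, the second with the glycine transporter gene slc6a5, held 829 and 576 and 254 and 1002 cells. Both matched a shared cluster of 643 and 920 cells (4.45% and 7.66%), at overlaps of 28.9% and 22.0%. Retinal ganglion-like cells with isl2b and pou4f2 numbered 126 and 126 (125 and 129 matched), cells with pax10 and tfap2c 229 and 158 (283 and 164), and motor-like cells with phox2a and chata 328 and 273 (135 and 198). Cells with dlx1a and gad2 numbered 278 and 181 (127 and 134 matched). Cluster 41, with epyc and chad, held 34 and 40 cells (31 and 40 matched), and cluster 26, with the lipoprotein genes apoa2 and apoa1b, 211 and 104 (82 and 57). The pvalb6 cluster 39 held 89 and 14 cells (283 and 164 matched, shared with the pax10 cluster, at an overlap of 22.2%). The foxn4 and insm1a cluster 42 held 6 and 52 (231 and 637, at an overlap of 5.59%), and cluster 44, with gng8, 28 and 5 (59 and 14). These clusters were compared by number because more than 90% of their cells came from 1 library, their names could not be given, or their class contained a cluster whose leading genes belonged to another class.

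**Figure D2:**
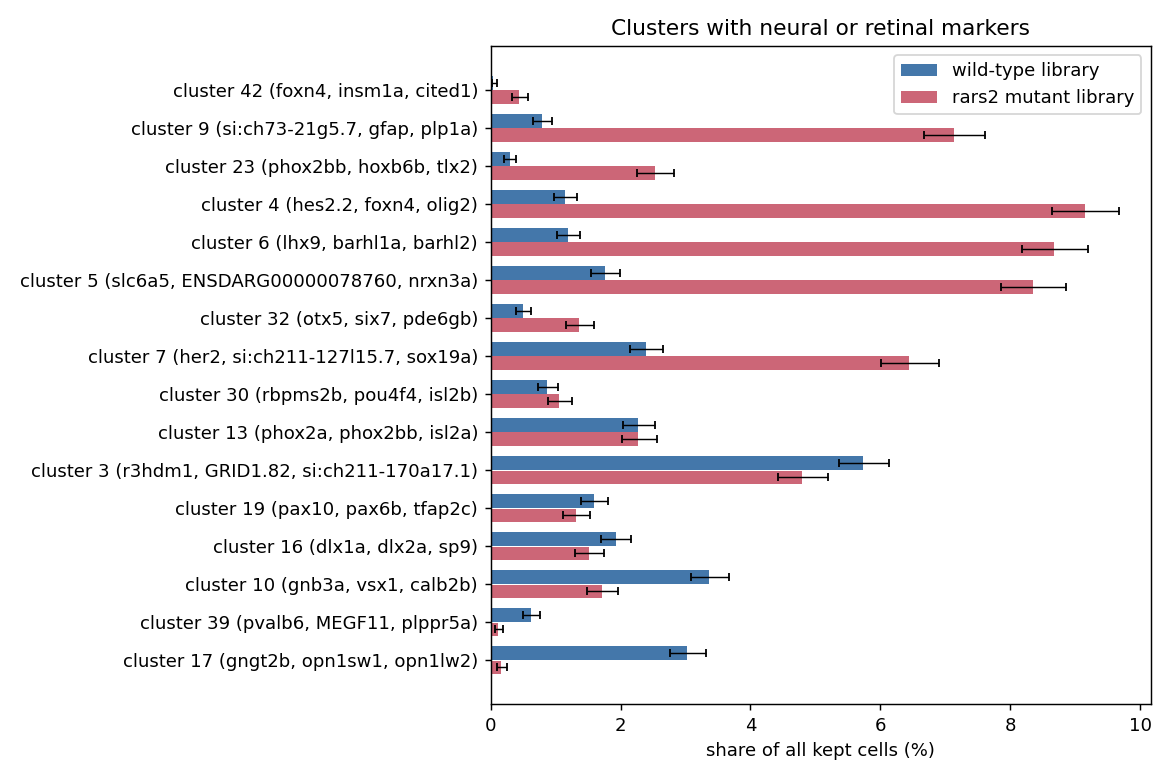
Share of all kept cells (percent, bars from 0) in 16 of the clusters with neural or retinal markers, without the small cluster 44, in the wild-type and the rars2 mutant library. Cluster 6 holds 171 wild-type and 1042 mutant cells, and cluster 17, with the opsin genes, 438 and 19.

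Among neural cells alone neural progenitor-like cells were 12.9% (11.8 to 14.0) in wild type and 23.9% (22.9 to 24.9) in the mutant. The log2 ratio was 0.89 (0.70 to 1.07), 1.3 when clustered without differing genes, 1.63 with marker scores per cell and 0.74 without sub-cluster 7, which carries mesenchyme genes. Different clusters held most of the class: cluster 7, led by her2 and sox19a, held 346 of the 460 wild-type cells, and cluster 9, led by gfap and her4.1, held 856 of the 1630 mutant cells. The matched clusters had 231 and 637 cells for cluster 7 and 179 and 833 cells for cluster 9. Retinal progenitor-like cells were 4.66% and 16.1% of neural cells, a log2 ratio of 1.79 (1.49 to 2.09), but -0.12 with marker scores per cell. The matched cluster held 139 and 659 cells.

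Neural cells were then clustered again into 27 sub-clusters, and once more without the genes that differed at least 1.5-fold over neural cells. Radial glia-like progenitors with ptn and slc1a2b were 3.06% of wild-type and 9.65% of mutant neural cells, and 3.09% and 9.11% in the matched sub-cluster. Cells with the excitatory-lineage genes lef1 and barhl1a were 2.08% and 5.64% (2.05% and 3.73% matched), and neuronal precursor-like cells with insm1a and dlb 1.49% and 4.07% (2.66% and 8.58% matched). Glycinergic-like neurons with otpa and slc6a5 were 4.57% and 10.1%, and midbrain-like neurons with tal1 and gata3 1.37% and 4.35%; both matched a shared sub-cluster of 4.04% and 7.79%. Spinal cord-like cells with posterior hox genes were 3.17% and 6.57%, but 6.48% and 6.56% in the matched sub-cluster. Lower shares were measured for vsx1 bipolar-like cells (13.4% and 2.88%, matched 10.9% and 2.97%) and cells with pvalb6 and grm6b (2.58% and 0.220%, matched 1.99% and 0.190%). The cells with pvalb6 and grm6b had only 4 of 8 amacrine and horizontal cell markers, so their type is left open. Shares were also lower for neurod6b telencephalon-like cells (2.97% and 1.51%, matched 2.08% and 0.644% at an overlap of 29.2%). Cells with th and dbh, genes of catecholamine synthesis, numbered 66 and 6 and matched no sub-cluster of their own. Sub-cluster 7, with collagen genes and a median of 1868 UMIs, held 414 wild-type and 127 mutant cells inside the neural clusters.

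Neural progenitor-like cells were more numerous in the mutant library, and UMIs of proliferation genes, not corrected for background, were detected in similar shares of them. After thinning to 2000 UMIs, mki67, a marker of dividing cells, was detected in 41.1% (36.2 to 46.1) of wild-type and 38.3% (35.8 to 40.9) of mutant neural progenitor-like cells. The topoisomerase gene top2a was detected in 19.1% and 18.3%, and the replication clamp gene pcna in 48.7% and 51.1%. Retinal progenitor-like cells gave 63.6% and 62.5% for mki67, 27.3% and 34.7% for top2a and 67.8% and 76.5% for pcna. In neuron clusters the shares were 10.5% and 16.1% for mki67, 5.77% and 6.66% for top2a and 14.0% and 23.3% for pcna. Thinning left out 68 and 200 neural progenitor-like cells and 23 and 151 retinal progenitor-like cells. Without thinning the neural progenitor-like shares were 52% and 53% for mki67, 33.7% and 34.3% for top2a and 62.0% and 66.3% for pcna, at medians of 5698.5 and 5014.5 UMIs, against 4432 and 4749.5 UMIs in neuron clusters.

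Over all neural cells, genes of dividing progenitors were higher in the mutant library and neuronal differentiation genes lower. Of 36 measured G2 and mitosis genes, 35 were higher by the size limit of the lists and 0 lower, with a median log2 ratio of 0.67 (0.63 to 0.73). Of 28 S phase genes, 25 were higher and 0 lower (median 0.59), among them the ribonucleotide reductase genes rrm1 at 2.46-fold (2.30 to 2.62) and rrm2 at 2.39-fold and the origin-licensing gene cdc6 at 2.09-fold. The spindle checkpoint genes bub1bb and mad2l1 were 2.17-fold and 1.86-fold higher and the mitotic cyclin gene ccnb1 2.1-fold higher. The median gene of all genes had a log2 ratio of -0.30 in neural cells, and lists are compared with it throughout. Relative to it the medians of these lists were 0.96 and 0.89, and each lay above all 10000 random lists matched on expression. With every neural cluster weighted equally in both libraries the medians were 0.27 for G2 and mitosis and 0.31 for S phase.

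Notch pathway genes, which keep progenitors from differentiating, were 22 of 31 higher and 6 lower, with a median of 0.78 (0.70 to 0.87) and 1.08 above the median gene. The Notch-driven repressor genes her15.1 (ENSDARG00000054562), her12 and her2 were 4.98-fold (4.78 to 5.20), 4.87-fold and 4.19-fold higher. Of 26 neural progenitor genes 16 were higher and 4 lower (17 and 0 relative to the median gene; median 0.71), with her4.2 at 3.11-fold; this list shares her15.1 and her12 with the Notch list and with the markers that name progenitor clusters. Of 28 proneural genes 16 were higher and 6 lower (median 0.60). The rhombic lip gene atoh1a (ENSDARG00000055294) was 5.18-fold (3.82 to 7.17) higher, from 46 and 484 UMIs, while neurod2 and neurod6a, which act in late neurons of the forebrain, were 5.25-fold and 4.45-fold lower. Equal cluster weights gave 0.39 for Notch genes, 0.21 for progenitor genes and 0.37 for proneural genes.

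Of 50 neuronal differentiation and synapse genes 3 were higher and 35 lower (6 and 25 relative to the median gene), with a median of -0.62 (-0.67 to -0.59). Cell adhesion gene cntn1b was 7.12-fold lower, synuclein gene sncga 6.1-fold lower and kinase gene camk2d1 3.71-fold lower. The list median lay 0.32 below the median gene and under all 10000 random lists, and was -0.34 with equal cluster weights. The list did not go lower in every group, with medians of -0.05 in cluster 3 (13 of 48 higher and 8 lower), 0.12 in cluster 6 (12 of 41 and 6), 0.47 in retinal progenitor-like cells (22 of 33 and 3) and 0.30 over all cells (25 of 51 and 12). Of 26 immediate early genes, which respond to activity and to dissociation, 2 were higher and 16 lower (4 and 14 relative to the median gene; median -0.76), with klf2b 6.84-fold, npas4a 5.10-fold and klf2a 3.89-fold lower.

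**Figure D3:**
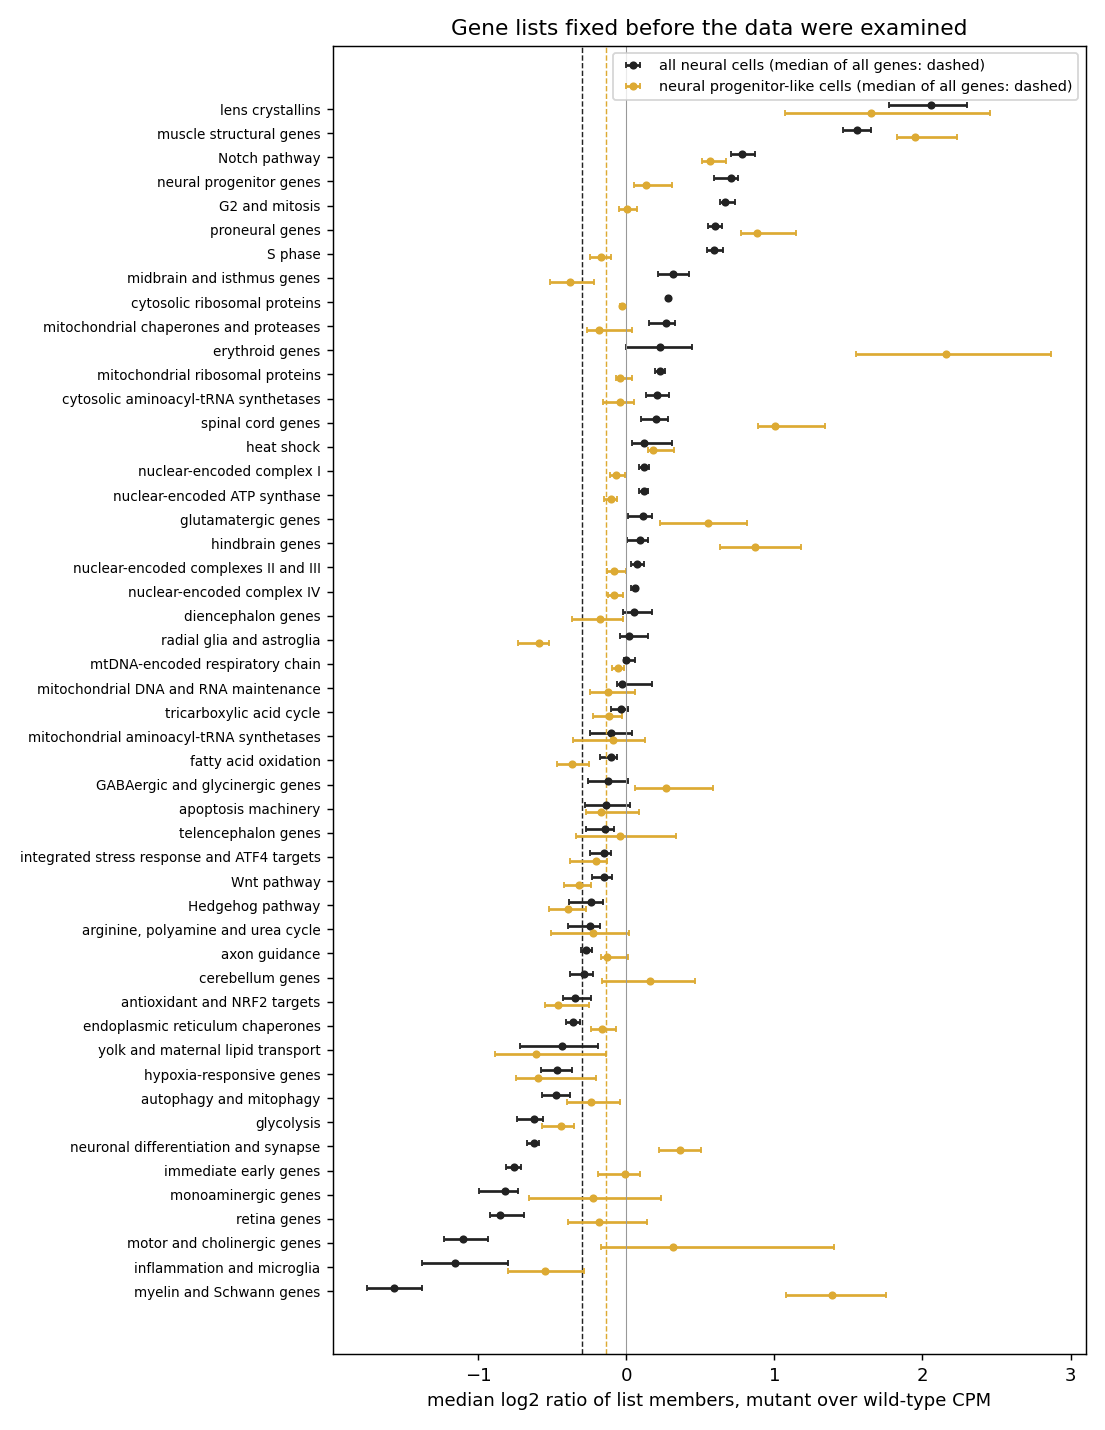
Median log2 ratio of mutant to wild type for each gene list in neural cells and in neural progenitor-like cells, with 95% counting intervals from 1000 Poisson draws; dashed lines mark the median of all genes in each set of cells. In neural cells the G2 and mitosis list lies at 0.67 and the neuronal differentiation list at -0.62.

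Within the neural progenitor-like class the cell cycle lists depended on how clusters were weighted, and proneural genes were higher. There the median gene had a log2 ratio of -0.14. G2 and mitosis genes had a median of 0.00, with 3 of 36 higher and 0 lower, and S phase genes -0.17, with 3 of 28 higher and 9 lower (3 and 2 relative to the median gene), or 0.40 and 0.12 with equal weights for clusters 7 and 9. Proneural genes were 20 of 24 higher and 1 lower (median 0.89, 0.78 to 1.14), and Notch genes 19 of 30 higher and 5 lower (median 0.57, or 0.32 with equal weights). Neuronal differentiation genes were 22 of 42 higher and 9 lower (median 0.36), the opposite side from all neural cells, but 0.06 without the barcodes of the highest doublet scores. Radial glia and astroglia genes were 2 of 18 higher and 11 lower (median -0.59, and -1.22 with equal weights). Genes of caudal regions were higher, with spinal cord genes 19 of 20 higher and 0 lower (median 1.00, or 0.29 with equal weights) and hindbrain genes 12 of 15 higher and 0 lower (0.87, or 0.43). Midbrain and isthmus genes were 5 of 19 higher and 10 lower (-0.38), Hedgehog genes 0 of 15 higher and 9 lower (-0.39), and Wnt genes 3 of 28 higher and 13 lower (-0.32). Neural progenitor genes themselves were 12 of 26 higher and 7 lower (12 and 4 relative to the median gene; 0.13), 0.27 above the median gene.

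Genes by the size rule in this class included transcripts of other tissues. The hatching enzyme gene he1.1 (ENSDARG00000023656) had 1 wild-type and 145 mutant UMIs, spread over 117 mutant cells, and the embryonic globin gene hbbe3 had 3 and 953 UMIs, of which 52.4% lay in 1 cell. The cartilage matrix gene matn1 was 34.1-fold lower. Globin gene hbae1.2 (13 and 1444 UMIs), star (0 and 275) and ENSDARG00000101479 (97 and 4) took 77.6%, 91.6% and 97.9% of their UMIs from 1 cell, asip2b (156 and 10) 51.3%, and atoh1c (112 and 9) came from 10 and 3 cells. The gene si:ch211-80h18.1 was lower at a log2 ratio of -5.32 and ENSDARG00000114516 was 19.4-fold higher (7.47 to 71.6).

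In cluster 6 the same rule named the ubiquitin ligase gene mdm2. It had 3 UMIs in 171 wild-type cells and 202 in 1042 mutant cells, 10.6-fold (3.56 to 51.7) higher, spread over 122 mutant cells. The neural crest gene foxd3 was 12.2-fold (4.12 to 59.5) higher and the neuronal homeobox gene tlx2 8.74-fold, each from 3 wild-type UMIs, and muscle gene tnnt3a 11.2-fold. Genes neurod2, fgfbp2b, zic5, CORO2B and brinp2 were 8.07-fold, 9.26-fold, 7.09-fold, 6.18-fold and 5.73-fold lower. In cluster 3 the rule named si:ch73-21g5.7 at 13.4-fold, mylpfb at 7.55-fold and hbbe1.2 at 7.12-fold higher, and si:ch211-224m9.4, retinoschisin gene rs1a and matn1 at 188-fold, 129-fold and 59.8-fold lower. Neuropeptide genes avp (0 and 267 UMIs), oxt (429 and 0) and npvf (176 and 0) were each carried by 1 cell for over 90% of their UMIs.

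Genes of the apoptosis machinery went in both directions in neural cells. The list was 3 of 19 higher and 7 lower (6 and 3 relative to the median gene; median -0.14), with pro-apoptotic bada 4.35-fold and bcl2l11 1.85-fold lower and birc5a, which also acts in mitosis, 1.83-fold higher. The ribosomal protein-like gene rps27l was 2.92-fold (2.69 to 3.16) higher.

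Stress programs often tied to faulty mitochondrial translation went in different directions in neural cells. Integrated stress response and ATF4 target genes were 3 of 36 higher and 14 lower, or 10 and 10 relative to the median gene. Their median was -0.15 (-0.25 to -0.10), 0.15 above the median gene, at the 78.27 percentile of random lists. The stress-induced transcription factor genes ddit3 and atf5a were 3.5-fold and 3.08-fold lower and the amino acid transporter gene slc3a2a 2.39-fold lower. Endoplasmic reticulum chaperone genes were 0 of 18 higher and 11 lower (0 and 5 relative to the median gene; median -0.36), with hsp90b1 and hspa5 1.75-fold and 1.70-fold lower and dnajc3a 1.99-fold lower. Mitochondrial chaperone and protease genes were 5 of 13 higher and 2 lower (7 and 0; median 0.27, or 0.13 without phb2a), 0.57 above the median gene and at the 99.30 percentile, with the prohibitin gene phb2a 2.02-fold and clpp 1.39-fold higher and clpxa 1.46-fold lower. Heat shock genes were 8 of 19 higher and 5 lower (11 and 1; median 0.12; 89.97 percentile), with hspa8b 3.07-fold and hspb1 2.01-fold higher and the collagen chaperone gene serpinh1b 2.84-fold lower. Antioxidant genes were 2 of 24 higher and 12 lower (7 and 8; median -0.34), with mt2, gpx4a and nqo1 3.57-fold, 2.28-fold and 2.24-fold lower. Autophagy and mitophagy genes were 0 of 22 higher and 14 lower (3 and 10; median -0.47), with ulk1a, pink1 and prkn 2.70-fold, 2.28-fold and 2.07-fold lower. The autophagy median was -0.29 with equal cluster weights, but 0.23 in cluster 3 (6 of 16 higher and 1 lower) and 0.21 in cluster 6 (2 of 13 and 0).

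Transcripts of the mitochondrial genome took nearly the same share of UMIs in neural cells of both libraries, 0.797% and 0.804%, a ratio of 1.01 (1.00 to 1.02). The ratio was 0.979 in neural progenitor-like and 0.847 in retinal progenitor-like cells. Lower shares were measured in mutant skeletal muscle-like cells (1.46% and 0.839%, a ratio of 0.576), erythroid-like cells (0.972% and 0.571%, 0.587) and macrophage-like cells (1.35% and 1.05%, 0.777), and over all cells the ratio was 0.925. Higher shares were measured in cluster 10 (ratio 1.13, 1.09 to 1.16), cluster 19 (1.12), cluster 5 (1.12, 1.09 to 1.15), cluster 6 (1.09), clusters 16 and 3 (1.07 in both) and fibroblast-like cells (1.06). Of the 13 respiratory chain transcripts, 1 was higher and 0 lower in neural cells (6 and 0 relative to the median gene; median 0.00). Complex I transcripts mt-nd1 and mt-nd2 were 1.28-fold and 1.24-fold higher, and mt-nd5 had a ratio of 0.883, which turned to a log2 ratio of 0.12 when scaled by the median gene.

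Nuclear genes for the respiratory chain stayed within the size limit for the most part over all neural cells, but leaned lower in retinal progenitor-like cells. Complex I had 1 of 42 higher and 1 lower (33 and 1 relative to the median gene; median 0.12), and complexes II and III 1 of 14 and 0 (10 and 0; 0.07). Complex IV had 0 of 16 and 4 (10 and 3; 0.06) and ATP synthase 1 of 18 and 1 (11 and 0; 0.12). Members that stood out were cox4i2, a hypoxia-linked isoform gene, and ndufa4b, 4.96-fold and 2.84-fold lower, cox4i1l and cox8b, 2.42-fold and 1.87-fold lower, and ndufa10, cycsb and atp5mc3a, 1.44-fold, 1.29-fold and 1.35-fold higher. The lower gene of the complex I list was ndufa4b, which entered by its nduf prefix and is assigned to complex IV. The higher gene of the complexes II and III list was cycsb, which encodes cytochrome c and is part of neither complex. Smaller differences were measured for ndufab1b and atp5f1b (1.21-fold and 1.22-fold higher), cyc1 (1.14-fold higher), atp5if1b (1.26-fold lower) and sdhb, which was 1.15-fold lower but had a log2 ratio of 0.10 when scaled by the median gene. With clusters mostly of 1 library counted among neural cells, the medians of complexes II and III, complex IV and ATP synthase were -0.04, -0.07 and -0.08. In retinal progenitor-like cells complex I had 1 of 41 higher and 12 lower (median -0.20) and ATP synthase 0 of 18 and 5 (-0.21), both under all random lists, and complex IV 1 of 12 and 2 (-0.18).

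Translation genes leaned higher over all neural cells, and the ribosomal lists less so in neural progenitor-like cells. Mitochondrial ribosomal protein genes were 23 of 75 higher and 0 lower (65 and 0 relative to the median gene), with a median of 0.23 (0.20 to 0.26) that lay above all random lists. Among them mrps28, mrpl10 and mrps27 were 1.61-fold, 1.52-fold and 1.43-fold higher. Cytosolic ribosomal protein genes were 29 of 83 higher and 2 lower (79 and 1; median 0.28), with rps8b and rps11l 2.41-fold and 1.45-fold lower, and cytosolic aminoacyl-tRNA synthetase genes 7 of 20 higher and 1 lower (16 and 1; 0.21). In this last list aimp1a, which is not itself a synthetase gene, and kars1 were 1.48-fold and 1.47-fold higher and mars1 1.72-fold lower. The mitochondrial aminoacyl-tRNA synthetase list, with genes of the family of rars2 and related genes, was 1 of 14 higher and 3 lower (5 and 1 relative to the median gene). Its median was -0.10 (-0.25 to 0.04), with wars2 1.42-fold higher and qrsl1 and sars2 2.70-fold and 1.49-fold lower. Of these qrsl1, also a leading gene of the erythroid-like cluster, encodes an amidotransferase subunit and not a synthetase. Mitochondrial DNA and RNA maintenance genes were 6 of 22 higher and 1 lower (11 and 0; median -0.03), with tsfm, gfm1 and fastkd2 1.51-fold, 1.46-fold and 1.44-fold higher. In neural progenitor-like cells the mitochondrial and cytosolic ribosomal lists had medians of -0.04 and -0.03, or 0.098 and 0.11 above the median gene. Over all cells the cytosolic ribosomal list was 2 of 83 higher and 3 lower, at the 5.14 percentile of random lists. The mitochondrial ribosomal list was 30 of 75 higher and 0 lower there.

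Glycolysis genes were lower over all neural cells, but not in every cluster. They were 6 of 27 higher and 18 lower (7 and 14 relative to the median gene), with a median of -0.62, or -0.41 with equal cluster weights, and -0.44 in neural progenitor-like cells, where 3 of 20 were higher and 15 lower (4 and 10 relative to the median gene). In cluster 3 they were 7 of 21 higher and 2 lower (median 0.12) and in cluster 6 they were 7 of 18 higher and 3 lower (0.26). The brain aldolase gene aldoca was 7.83-fold lower, while pfkmb and pgam2, isoform genes of muscle, were 3.72-fold and 3.35-fold higher. The log2 ratio of pgam2 became -2.13 after a background profile was subtracted. Hypoxia-responsive genes were 1 of 20 higher and 11 lower (3 and 8; median -0.47), at the 24.76 percentile of random lists, with pdk2b, adma and ndrg1a 4.78-fold, 3.65-fold and 2.57-fold lower. Tricarboxylic acid cycle genes were 1 of 22 higher and 4 lower (9 and 2; -0.03), with the pyruvate carboxylase genes pcxb and pcxa 3.62-fold and 1.58-fold lower and ogdha 1.43-fold lower. Fatty acid oxidation genes were 0 of 20 higher and 5 lower (3 and 2; -0.10), with the carnitine transferase gene cpt1ab, decr1 and hadhaa 2.27-fold, 1.61-fold and 1.48-fold lower. Arginine, polyamine and urea cycle genes, tied to the amino acid that the rars2 enzyme uses, were 3 of 21 higher and 10 lower (7 and 7; -0.25), with sat1a.1, nos1 and the arginine transporter gene slc7a1a 4.42-fold, 3.40-fold and 2.09-fold lower. The arginine list had medians of 0.12 in cluster 3 and 0.29 in cluster 6.

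Regional and transmitter genes of neural cells went in different directions. Midbrain and isthmus genes were 11 of 22 higher and 1 lower (17 and 0 relative to the median gene; median 0.31), with tal2, wnt1 and gata2a 2.37-fold, 2.02-fold and 1.86-fold higher, and spinal cord genes 6 of 20 higher and 3 lower (13 and 1; 0.20). The homeobox genes hoxb6b and hoxc6b were 1.88-fold and 1.65-fold higher and hoxc10a 1.58-fold lower. With equal cluster weights these medians were -0.07 and -0.40, and the midbrain list had -0.12 in cluster 3 and -0.52 in cluster 6. Hindbrain genes were 6 of 18 higher and 5 lower (10 and 3; 0.09, or -0.07 with equal weights), with egr2a 2.28-fold higher and irx7 and phox2a 2.35-fold and 2.32-fold lower. Cerebellum genes, the region named in the human disorder, were 8 of 27 higher and 13 lower (11 and 8; median -0.28, 0.01 above the median gene). Their early members atoh1a and ptf1a, which specify glutamatergic and GABAergic cerebellar cells, were 5.18-fold and 3.72-fold (2.70 to 5.24) higher. The Purkinje cell gene pvalb7 was 3.58-fold lower. These folds are over all neural cells, retinal clusters included, so they need not lie in cerebellar cells. In neural progenitor-like cells the related gene atoh1c was lower, with 112 and 9 UMIs from 10 and 3 cells. Telencephalon genes were 4 of 17 higher and 6 lower (5 and 3; -0.14, or 0.12 with equal weights), with six3b 1.82-fold lower and sp8a 1.75-fold higher. Diencephalon genes were 5 of 20 higher and 6 lower (10 and 2; 0.06), with otpa and otpb 2.59-fold and 2.31-fold higher and fezf2 2.52-fold lower.

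Motor and cholinergic genes were 0 of 10 higher and 8 lower (1 and 7 relative to the median gene), with a median of -1.10 that was -0.11 with equal cluster weights. Acetylcholine synthesis gene chata, lhx4 and isl2b were 2.91-fold, 2.85-fold and 2.69-fold lower. Monoaminergic genes were 3 of 14 higher and 9 lower (median -0.82), with ddc, tph1a and slc18a2 5.26-fold, 5.23-fold and 4.09-fold lower. The monoaminergic median was -0.50 with equal cluster weights, but 0.43 in cluster 3 (6 of 10 higher and 1 lower) and 0.83 in cluster 6 (5 of 7 and 0). GABAergic and glycinergic genes were 8 of 17 higher and 8 lower (8 and 2 relative to the median gene; -0.12), with the GABA transporter gene slc6a1a 3.56-fold lower and lhx5 2.18-fold higher. Glutamatergic genes were 4 of 17 higher and 5 lower (9 and 3; 0.11), with the vesicular transporter genes slc17a7a and slc17a8 9.38-fold and 3.23-fold lower and tlx1 3.71-fold higher. Axon guidance genes were 5 of 41 higher and 18 lower (13 and 10; -0.27), with sema6d, cxcl12a and slit2 3.15-fold, 2.97-fold and 2.27-fold lower. Radial glia and astroglia genes were 7 of 18 higher and 7 lower (9 and 4; median 0.02, or -0.53 with equal weights), with fabp7b, mfge8a and the glutamine synthetase gene glula 4.96-fold, 3.5-fold and 3.35-fold lower. Retina genes were 5 of 28 higher and 19 lower (7 and 15; -0.85, or -0.18 with equal weights). The opsin genes opn1sw1 (602 and 5 UMIs) and rho (580 and 6), and gnat2 at 3.14-fold lower, are genes of photoreceptors, most of which were in a cluster not counted among neural cells.

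Among signalling lists, Hedgehog genes were 3 of 16 higher and 8 lower (5 and 3 relative to the median gene; median -0.24, or 0.06 when scaled by the median gene). Hedgehog-induced ptch1 and hhip were 1.84-fold and 1.83-fold lower and nkx6.1 1.77-fold higher. Wnt genes were 4 of 31 higher and 14 lower (11 and 9; -0.15, or 0.15 when scaled by the median gene), with sfrp2 and tcf7 5.28-fold and 2.82-fold lower and sp5l 3.60-fold higher.

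Transcripts of other tissues also differed inside neural cells. Lens crystallin genes were 19 of 20 higher and 1 lower (median 2.06), with cryba2a 6.89-fold (3.84 to 13.6), crygm2d12 6.03-fold and crygm2d18 5.90-fold higher. Muscle structural genes were 22 of 28 higher and 4 lower (median 1.56), with pvalb3 16-fold, mylpfb 6.66-fold and myhz1.3 6.06-fold higher, and the median was 0.81 with a background profile subtracted. Erythroid genes were 9 of 18 higher and 5 lower (11 and 2 relative to the median gene; median 0.23, or -0.06 with background subtracted). Globin genes hbbe3 (13 and 2272 UMIs), hbbe1.2 and hbae1.1 were 86.0-fold, 4.61-fold and 3.28-fold higher. Myelin and Schwann genes were 3 of 12 higher and 9 lower (median -1.57), with mbpa (134 and 2 UMIs), cldnk (71 and 2) and mag (126 and 25). Microglia genes were 0 of 13 higher and 8 lower (2 and 8; median -1.15, or 0.23 with background subtracted), with mpeg1.1, csf1ra and csf1rb 4.17-fold, 3.52-fold and 3.10-fold lower. Yolk and lipid transport genes were 1 of 8 higher and 4 lower (2 and 4; median -0.43), with apoa1b, mttp and apoa2 2.11-fold, 1.76-fold and 1.66-fold lower.

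The rule for genes that differed in most of the cell groups where they were measured, run over 21 groups and 13135 genes, named transcripts of several tissues. The groups measured ranged from 5 for ccndx to 21 for hbbe1.2, with 7 for he1.1 and rho. The highest medians over groups were those of hbbe3 (46.6-fold), he1.1 (14.0-fold), ENSDARG00000114516 (11.7-fold), si:ch211-57n23.4 (8.02-fold), ccndx (7.41-fold), hbbe1.2 (6.93-fold), plp1a (6.91-fold), si:ch73-21g5.7 (6.86-fold), mylpfb (6.85-fold) and atoh7 (6.37-fold). The lowest were those of rho (48.5-fold lower), matn1 (31.7-fold), myhb (27-fold), lgals2b (26.2-fold), opn1sw1 (23.8-fold), acta2 (18.2-fold), si:dkey-183i3.5 (17.9-fold), rs1a (17.2-fold), col8a2 (13.6-fold) and pvalb6 (13.6-fold). A group with 0 UMIs in 1 library was set against 3 UMIs, which applied to 11 of 15 groups for opn1sw1, 3 of 7 for rho and 5 of 18 for matn1, so such folds are bounds and the order of the genes is not fixed. Their levels in the median of all 21 groups, also groups with too few UMIs to be measured, were 0.0584 to 0.390 of those in barcodes with fewer than 500 genes. Among the lower genes rho and opn1sw1 are opsin genes of rods and cones, matn1 encodes a cartilage matrix protein and acta2 smooth muscle actin. Among the higher genes hbbe3 and hbbe1.2 encode embryonic globins, he1.1 an enzyme of the hatching gland, mylpfb a muscle myosin light chain and atoh7 a regulator of retinal neurogenesis.

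The size rule was also applied to the largest classes outside the nervous system. Fibroblast-like cells had the Notch-driven gene her12 at 9.77-fold (6.84 to 14.3) and ABHD6 at 8.39-fold higher, and ifitm1 and epd at 70.5-fold and 78.1-fold lower. Fin fold-like cells had cart3 at 12.2-fold (8.83 to 17.1), ptgdsb.1 at 10.1-fold and krt97 at 8.76-fold higher, and col8a2 at 19.5-fold lower, with hamp and ifitm5 carried for 82.7% and 56.1% of mutant UMIs by 1 cell. Pharyngeal arch-like cells had her15.1 at 7.20-fold (4.98 to 10.8) higher and crip1, ifitm1 and si:ch211-106h4.12 at 26.5-fold, 56.3-fold and 104-fold lower, with sst1.1 and HYAL4 mostly in 1 cell. The gene si:ch211-106h4.12 was also 26.6-fold lower in fin fold-like cells, and asip1 had 121 wild-type and 0 mutant UMIs there. All 3 classes also had matn1 lower, and fibroblast-like and fin fold-like cells opn1sw1. The genes her12, ABHD6 and her15.1 are leading genes of neural progenitor-like clusters. They were also higher in mutant barcodes removed for few genes, at log2 ratios of 2.77, 3.09 and 2.94. Free RNA could therefore give their higher levels in fibroblast-like and pharyngeal arch-like cells, which was not tested.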

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

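The tests of broad genes, of tissue yield and of embryo age were chosen only after the result was seen. The hatching enzyme gene he1.1 had 351 UMIs in mutant barcodes with fewer than 500 genes, which the comparisons do not use, against 6 in wild type, a signal outside the main measurement.

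Genes that differed in most of the cell groups where they were measured included transcripts of blood, hatching gland, cartilage and muscle. They also included genes such as plp1a and atoh7 that lead neural clusters. A first version of the test, replaced after its outcome was seen, asked whether they went the same way in barcodes with fewer than 500 genes, which held for 20 of 20 and could not tell free RNA from true expression. Compared by level, the median over the 20 genes was 0.214 of their CPM in those barcodes (0.0584 to 0.390), with all 20 under the limit of 0.5 set for free RNA. Of them 7 lay above the largest background share of 23.8%, which was estimated in neural groups only. The level was the median over all 21 groups, also those with too few UMIs of a gene. A gene expressed in few groups is low there whatever the cause, so this test cannot decide either. Those barcodes had at least 500 UMIs and may include shallow cells. Free RNA stays a candidate explanation that these levels do not decide, and it would carry over a true difference in the source tissues, which stays open. The levels did not set genes of neural clusters apart. Genes above the background share included atoh7 (0.390) but also matn1 (0.373) and acta2 (0.312), and plp1a lay at 0.229.

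More progenitors and fewer late cells were found in the mutant library. A lower yield of non-neural tissues does not account for all of the difference in progenitors. Their share of neural cells alone had a log2 ratio of 0.887, and 0.74 (0.56 to 0.92) without a sub-cluster with mesenchyme genes. Of all cells it was 2.09, so part of the difference went with the neural share. Unequal yield among neural cells cannot be told from these shares and was not tested. Pools of different age could give the pattern, since he1.1, a gene used up to hatching, was 60.2-fold (27.4 to 165) higher in mutant barcodes with fewer than 500 genes. In the same barcodes opn1sw1, rho and mbpa had 247, 127 and 71 UMIs in wild type and 0 in the mutant and mbpb 153 and 29, but the muscle genes pvalb1 and mylpfa were 4.70-fold and 3.75-fold higher, which a younger pool does not simply predict. Slower development of mutant embryos predicts the same values as a younger pool, so the explanation stays open.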

How the results depend on the processing

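The alternatives on doublet scores, clusters mostly of 1 library, earlier naming rules, low-depth clusters, the mesenchyme-marked sub-cluster and background subtraction were chosen only after the result was seen. No paired analysis was possible because the groups share only the number 1. Keeping called doublets was not run, since none was called. Values are log2 ratios of mutant to wild type, and the cause of each difference was not tested unless stated. The neural share kept its direction in all 14 alternatives (0.64 to 1.44), neural progenitor-like cells too (1.96 to 2.84), and their share of neural cells as well (0.70 to 1.63). Scaling by the median gene moves every list and gene by the same amount, so it is left out of the next counts. Among list medians, 143 of those in neural cells left the counting interval, 10 turned and 508 stayed within it, and in neural progenitor-like cells 63, 11 and 576. Of single genes 375 moved, 5 turned and 1747 stayed. Percentiles moved in 7 cases and stayed in 95. Ranges of other classes over the alternatives were -2.62 to -1.14 for fibroblast-like cells (-1.21 in the text), -2.69 to -1.38 for ionocyte-like (-2.03), -1.3 to -0.30 for muscle progenitor-like (-1.04), -3.65 to -1.77 for neutrophil-like (-2.72) and -2.38 to -0.56 for otic-like cells (-2.15). They were -2.33 to -0.33 for periderm-like (-1.88), -1.02 to 0.030 for pigment cell-like (-0.27), -2.79 to -1.59 for smooth muscle-like (-2.75) and -0.23 to 0.82 for floor plate-like cells (0.58).

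Cell filters and clustering moved the neural share of all cells from 1.21 to 1.32 (at least 1000 genes and at most 10% mtDNA), 1.01 (resolution 0.8), 1.44 (resolution 2.5), 0.71 (without differing genes), 1.32 (wild-type clusters transferred), 1.04 (clusters mostly of 1 library kept in their classes), 0.64 and 1.08 (versions 1 and 2 of the naming rule) and 1.36 (without the mesenchyme-marked sub-cluster). The neural progenitor-like share moved from 2.09 to 2.44 with transfer and 2.84 with marker scores per cell, and the retinal progenitor-like share from 2.99 to 1.09 with those scores. Among neural cells the progenitor share moved from 0.89 to 1.3 (without differing genes), 1.13 (transfer), 1.63 (marker scores), 0.70 (highest 8% of doublet scores removed) and 1.45 (version 1), and the retinal progenitor share from 1.79 to 1.45 (resolution 2.5) and -0.12 (marker scores). Erythroid-like cells turned from -0.67 to 2.55 (resolution 0.8) and 1.51 (marker scores). Pharyngeal arch-like cells turned from 0.90 to -1.33 (resolution 0.8), -1.33 (without differing genes), -0.84 (transfer), -0.86 (marker scores) and -1.3 (clusters mostly of 1 library kept, which adds an arch cluster of wild-type cells).

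Scaling by the median gene adds 0.30 in neural cells by construction. It gave 1.08 for Notch, -0.32 for neuronal differentiation, 0.31 for the mtDNA share and 0.58 for rars2 (0.33 before). It turned the integrated stress response to 0.15, fatty acid oxidation to 0.20, Hedgehog to 0.058, Wnt to 0.15, axon guidance to 0.029, telencephalon to 0.16, cerebellum to 0.014, arginine genes to 0.051, mt-nd5 to 0.12 and sdhb to 0.096. In neural progenitor-like cells it turned the mtDNA-encoded chain to 0.084, complex I to 0.069, complex IV to 0.052, ATP synthase to 0.038, cytosolic ribosomal proteins to 0.11 and the tricarboxylic acid cycle to 0.018. Totals without mitochondrial, ribosomal and hemoglobin genes gave 0.070 for the mtDNA share, -0.094 for the integrated stress response and -0.57 for neuronal differentiation.

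Equal cluster weights gave 0.39 for Notch, -0.34 for neuronal differentiation, -0.35 for the integrated stress response and 0.067 for the mtDNA share. They turned complex IV to -0.018, telencephalon to 0.12, midbrain to -0.069, hindbrain to -0.074 and spinal cord to -0.40, and in neural progenitor-like cells the mtDNA-encoded chain to 0.021, complex I to 0.043, cytosolic ribosomal proteins to 0.16 and S phase to 0.12. Clusters mostly of 1 library, kept in their classes, gave the reverse sign of -0.036 for the mtDNA share, -0.038 for complexes II and III, -0.067 for complex IV and -0.077 for ATP synthase, with 0.88 for Notch and -0.53 for neuronal differentiation. Removing the highest 8% of doublet scores gave 0.70 for Notch.

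Thinning to 2000 UMIs gave 0.033 for the mtDNA share, -0.083 for the integrated stress response, 0.90 for Notch and a reversed -0.77 for glutamatergic genes in neural progenitor-like cells, and thinning to 1000 UMIs gave -0.21 for pcna there. Weighting each cell equally turned the mtDNA share to -0.012 and, in neural progenitor-like cells, complex I to 0.054, cytosolic ribosomal proteins to 0.027 and GABAergic genes to -0.047. The stricter cell filter gave 0.025 for the mtDNA share (0.013 in the text). List members with at least 200 UMIs gave 0.96 for Notch and a reversed -0.66 for glutamatergic genes in neural progenitor-like cells, and members with at least 1 UMI a reversed -1.27 for myelin genes there. Background subtraction gave -0.78 for neuronal differentiation and turned erythroid genes to -0.058, microglia genes to 0.23, mt-nd5 to 0.27, pgam2 to -2.13, hbae1.1 to -3.75, mpeg1.1 to 0.78, csf1ra to 1.85 and, in neural progenitor-like cells, the mtDNA-encoded chain to 0.14. In those cells it raised the erythroid list from 2.16 to 2.99, so it did not remove that signal everywhere.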

Other observations

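These values and the choice of genes came after the data were seen, and no test was run on them. Genes outside the naming rule also differed in neural cells. The proneural gene neurog1 had 324 UMIs in wild type and 2039 in the mutant, or 18.9 and 58.4 CPM, and the synaptic vesicle gene syt1a 8934 and 7841 UMIs, or 520 and 224 CPM. In neural progenitor-like cells the neurogenic gene neurod4 had 91 and 1118 UMIs, a log2 ratio of 1.93. The midbrain boundary gene en2a had 286 and 362 UMIs, a log2 ratio of -1.35, and the glutamate transporter gene slc1a2b 1543 and 2025, a log2 ratio of -1.29.

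Barcodes with fewer than 500 genes carried muscle and blood transcripts at higher levels in the mutant library. The parvalbumin gene pvalb1 had 972 and 4440 UMIs there, the myosin gene mylpfa 672 and 2447 and the globin gene hbbe1.3 397 and 1597. Cartilage transcripts were lower, with 253 and 3 UMIs of matn1 and 660 and 147 of col11a2.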
